A study of Gallus gallus with 6 samples.

How the data were processed

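The series holds 6 ileum libraries of Taiping chicken, 3 control and 3 FOS, grouped by their sample titles. Per the labels' protocols, total RNA was extracted with TRIzol and the kit named for the libraries is one for small RNA, although the table covers genes of all kinds. The submitters' processing notes name fastp 0.18.0, Bowtie2, HISAT2, StringTie and DESeq2, with no roles. The genome build and the counting step are not given in the sources used here, so no coordinates are printed.

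The authors deposited a table of 17623 rows, 16568 Ensembl gene IDs and 1055 loci assembled from reads, with expected counts (estimated counts that need not be whole) and FPKM for each library. Of the deposited count values 8.06% were not whole at a tolerance of 1e-09, and counts were rounded to whole numbers before count tests. The ratio of counts to FPKM over 3690 genes with FPKM above 20 in every library gave the relative depth of each library, which equalled the relative total of the deposited counts to 4 digits. The planned comparison of counts per kilobase with FPKM was not made because the table gives no gene lengths. The table also has 12 value columns for 6 libraries that are not among the samples described, and these columns were not used. Names come from the table for 12776 rows and, through NCBI gene IDs, from RefSeq gene names of the assembly GRCg7b for 1108 more (13650 of 13969 gene IDs matched); 3739 rows stayed unnamed. Names of assembled loci, such as MUC2, CDX2 and NPC1L1, rest on the authors' annotation, which for some points to predicted genes of other birds. Of 1394 list members 1237 were found. Reads shared by paralogs or by W-linked genes and their Z-linked partners may be split by the authors' counting, so values of such genes are uncertain.

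Genes were kept by filterByExpr (13807 kept, 829 of them assembled loci), scaled by TMM and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, without covariates, with Benjamini-Hochberg adjustment and a threshold of 0.05. SE is the log2 fold change divided by the root of the F statistic. CPM values use TMM-scaled library sizes. The common biological coefficient of variation was 24.6%. The 43 gene lists, the rule for named genes and the alternatives not marked as added were written before the data were examined. Lists with at least 5 kept members were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry (limma 3.58.1); annotated pathways with 10 to 300 kept genes were tested in the same way. Library measures were compared by two-sided exact permutation tests. Intervals and floors cover counting error only.

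On simulated counts for FOS against control, with 200 genes changed among 13646 tested, edgeR called 3% of genes changed 1.5-fold, 32.8% of those changed 2-fold and 92.4% of those changed 4-fold, with 3 false calls among 88. DESeq2 1.42.0 called 20.9%, 62.7% and 93.9%, with 36 false calls among 154. With 1 list of 42 raised 1.5-fold, camera with either correlation and fry called that list and 0 others; genes were simulated as independent.

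The rule for named genes took genes with a symbol that passed the test, did not overlap between groups and had a mean of at least 1 CPM, up to 14 per direction by fold change. It was filled to 10 per direction by unadjusted p and added up to 4 members with the smallest p of each called list, 10 genes always given, and up to 2 unnamed loci per direction. It gave 91 genes. HINTW is named Wpkci-7 in the table. SPIN1W, HNRNPKL, ATP5F1AW and the genes of the last part that fall outside the rule were chosen after their values were seen.

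Replicate numbers come from the sample titles. Deviations from group means correlated at 0.24, 0.388 and 0.198 for the 3 same-numbered pairs, all over 0.1, so the numbers met the bar for pairs. The test stayed without the block, as planned, and the block was an alternative. Without 61 genes that differed by at least 2 log2 units between every library with W-linked transcripts and every library without, these were 0.156, 0.048 and 0.075, so that 1 of 3 stayed over 0.1. A broader definition of these genes had been tried first. No label says what a number marks.

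Alternatives were RLE and upper-quartile factors, library sizes without the 20 most abundant and the mitochondrial genes, no filter, a stricter filter (at least 1 CPM in 3 libraries), DESeq2, limma-voom with and without quality weights, limma on log2(FPKM + 1) or log2(FPKM + 0.1), a fold threshold of 2, assembled loci without a symbol left out, each library left out in turn, and the replicate number as a block. After the data were examined, 5 more were added: presence of W-linked transcripts (HINTW above 10 CPM) as a covariate, only the 4 libraries with them, robust empirical Bayes, the mean level of the smooth muscle list as a covariate, and DESeq2 with the block.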

Results

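Messenger RNA was profiled in the ileum, the last part of the small intestine, of Taiping chickens aged 2 months. Control birds received a basal diet of corn and soybean, and the other birds received it with fructooligosaccharide, a chain of fructose units that gut bacteria ferment, at 1 mL per litre of drinking water. FOS stands below for this supplement and its group, never for the gene of that name. Each group had 3 libraries. Total deposited counts were 16056240, 17289705 and 18106651 in control 1 to 3 and 15641456, 14668289 and 17793586 in FOS 1 to 3. Before TMM scaling of the library sizes, 1 CPM (counts-per-million, a read count normalised to library size) stood for 14.7 to 18.1 counts. The CPM values given below use the scaled sizes, so their count per CPM differs somewhat. The share of counts in the 20 most abundant genes was 11.7% ± 0.541 (SD, n = 3) in control and 12.5% ± 1.05 (SD, n = 3) in FOS, a difference with p = 0.4 in a two-sided exact permutation test, where 0.1 is the smallest p that 3 against 3 can give. The labels do not say that the libraries of a group came from separate birds, so p-values measure the spread between these libraries.

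The labels name every bird as male, and males carry no W chromosome. Transcripts of HINTW, a W-linked gene, stood at 146 and 149 CPM in control 1 and control 3 and at 158 and 111 CPM in FOS 1 and FOS 3. In control 2 and FOS 2 they stood at 0.173 CPM (3 counts) and 0.0696 CPM (1 count). The W-linked genes SPIN1W, HNRNPKL and ATP5F1AW had the same pattern, so 4 of 6 libraries held W-linked transcripts, 2 in each group. These values argue against the male label for those 4 libraries. The first principal component, with 41.7% of the variance of the 1000 most variable genes, separated control 2 and FOS 2 from the other 4 libraries. Once 61 genes that followed this split were left out, FOS 1 stood apart from the other 5 libraries on the first component, which held 30% of the variance. Mean correlation between groups minus that within groups was 0.0129 in the 1000 most variable genes (exact permutation over 10 splits, one-sided p = 0.5). Over all genes tested it was -0.00201 (exact one-sided p = 0.2), the other sign, and the design cannot give a p under 0.1.

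**Figure D1:**
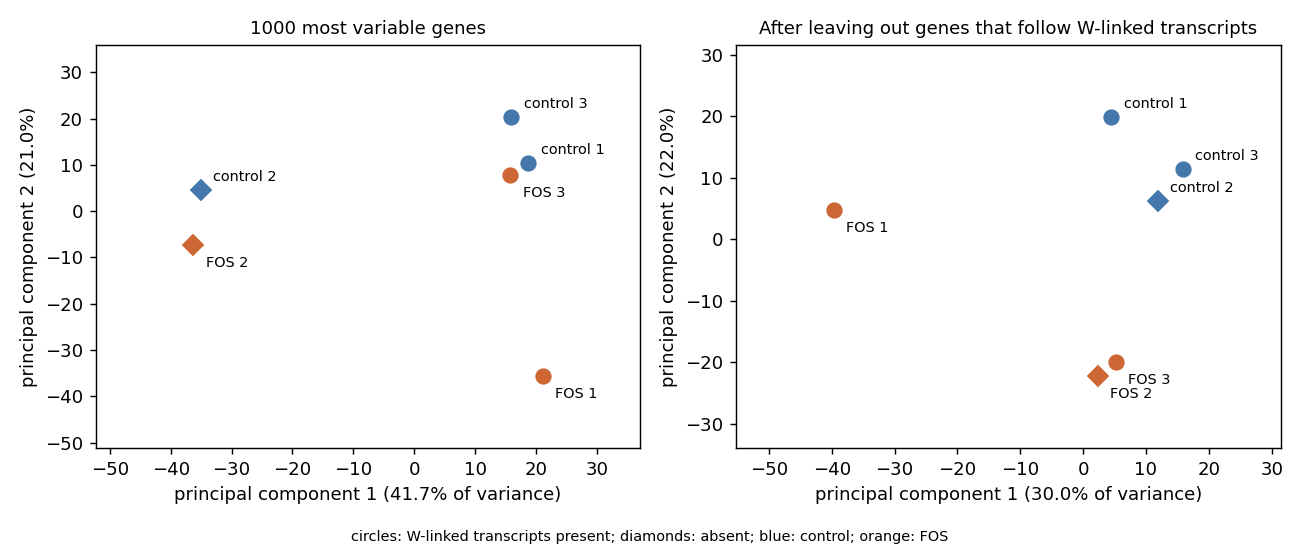
Principal components of log2 CPM, with component 1 across and component 2 up, for the 1000 most variable genes (left) and for the 1000 most variable after 61 genes that followed the W-linked transcripts were left out (right). Each point is a library; on the left control 2 and FOS 2 lie at -35.07 and -36.25 on component 1, and on the right FOS 1 lies at -39.68.

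The main question was which ileal transcripts differed between birds given FOS and control birds. NPAS2 (ENSGALG00000016774), a transcription factor of the circadian clock, rose from 22.9 ± 3.29 CPM in control to 109 ± 10.5 CPM in FOS (SD, n = 3), a log2 fold change of 2.25 (SE 0.14, edgeR adjusted p = 0.00625). ASAH2 (ENSGALG00000003751), a ceramidase of the intestinal brush border, rose from 8.03 ± 0.692 to 50.6 ± 12.1 CPM (SD, n = 3), a log2 fold change of 2.65 (SE 0.2, edgeR adjusted p = 0.00917). MSTRG.8228, a locus that was assembled from reads and has no gene name in the table, held 0, 2 and 6 counts in control 1 to 3 and 839, 677 and 1690 counts in FOS 1 to 3. Its ratio of FOS to control was 450 (95% exact binomial counting interval 228 to 1042), and without control 3, which left 2 control counts, 1158 (interval 320 to 9567). Its edgeR adjusted p was 0.00625. The 0 counts in control 1 allow up to 0.18 CPM (3 counts). These 3 genes, all higher in FOS, were the calls among 13807 genes tested, and 0 genes were called lower. At an unadjusted p under 0.05 there were 710 genes higher and 590 lower, where 690 in all would be expected by chance. The groups did not overlap in 16.4% of genes. Without ties this share averages 10% over the 10 possible splits by construction, so some splits can exceed it. The share in the other splits is not given here, so 16.4% is not shown to be beyond chance. DESeq2 called 149 genes, 105 higher and 44 lower, or 115 with the replicate number as a block, and limma-voom called 1. Without control 1, 2 or 3 the edgeR adjusted p of NPAS2 was 0.0719, 0.0384 and 0.0518, that of ASAH2 0.075, 0.113 and 0.153, and that of MSTRG.8228 0.0581, 0.0998 and 0.0518, so that 0, 1 and 0 genes were called.

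Clock genes differed in both directions. Of the 23 clock list members measured, 2 rose and 7 fell with p adjusted over the list alone, and edgeR called 1 over all genes, NPAS2. DESeq2 called 7 members over all genes, 2 higher and 5 lower (2 and 4 with the block), and limma-voom called 1. ARNTL, the partner of CLOCK and NPAS2, rose from 20.9 ± 1.43 to 39.1 ± 4.55 CPM (SD, n = 3). Genes that repress the clock fell: PER3 from 30.7 ± 6.09 to 8.77 ± 0.765 CPM, PER2 from 193 ± 37.2 to 79.6 ± 12.9 CPM, and NR1D2 from 116 ± 16.9 to 52 ± 8.42 CPM (SD, n = 3). Over all genes PER3 had an edgeR adjusted p of 0.0638, and 0.049 when no filter on low counts was applied (1.23e-12 to 0.43 over all alternatives). NR1D1, HLF, BHLHE40 and CIART also fell with p adjusted over the list alone, CIART from 1.3 ± 0.36 to 0.182 ± 0.17 CPM (SD, n = 3). CLOCK itself stood at 55.3 ± 1.57 and 53.5 ± 7.69 CPM (SD, n = 3). The list as a whole was called lower by camera (median log2 fold change -0.15, and -0.09 without control 3; adjusted p = 0.0025), while its adjusted p was 0.35 with an estimated correlation. Fry's test for change in either direction called the list (adjusted p = 0.000168), while its test for change on balance in 1 direction gave an adjusted p of 0.186. With only the 4 libraries that held W-linked transcripts the camera adjusted p was 0.0761 (0.000477 to 0.35 over all alternatives).

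**Figure D2:**
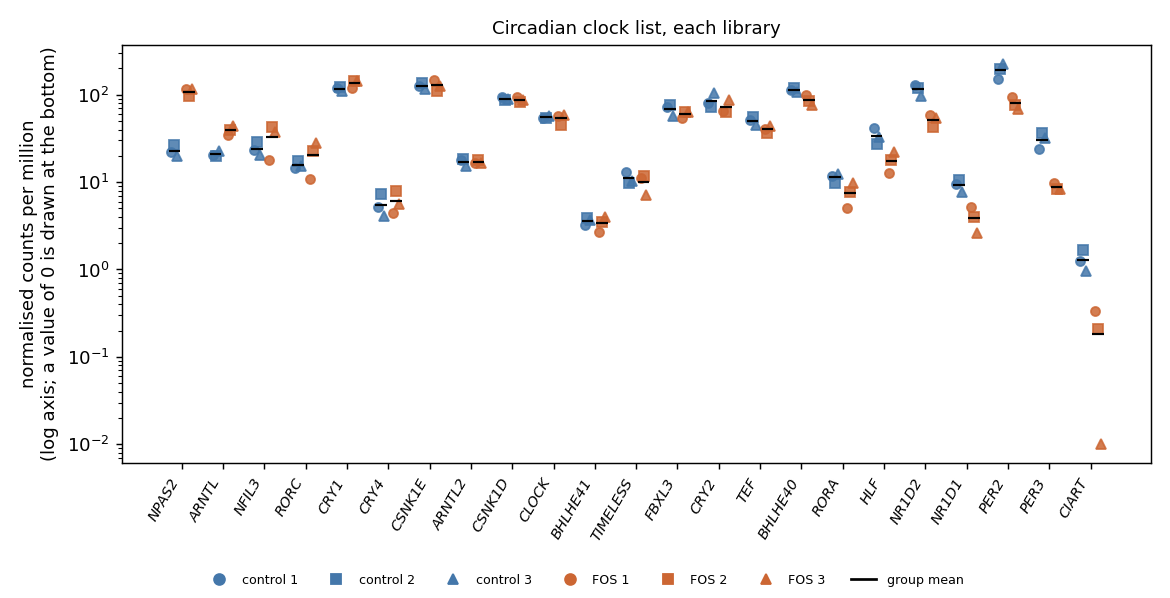
Normalised read count (CPM) on a log axis for the 23 measured clock genes, ordered by log2 fold change, with a symbol for each library and a bar at each group mean. NPAS2 lies at 22.9 CPM in control and 109 CPM in FOS, and PER3 at 30.7 and 8.77 CPM; a value of 0 is drawn at the bottom.

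Genes of cholesterol synthesis and uptake were higher in FOS: 12 of 24 measured members rose and 0 fell with p adjusted over the list alone, and edgeR called 0 over all genes. At an unadjusted p under 0.05 edgeR had 14 members, and over all genes DESeq2 called 4, all higher (2 with the block, LSS and MSMO1), and limma-voom 0. The median log2 fold change was 0.61. The mean log2 CPM of the list was 6.18, 5.93 and 5.58 in FOS 1 to 3 and 5.25 to 5.46 in control. LSS, which closes the sterol ring, rose from 71.6 ± 13.3 to 133 ± 22.6 CPM (SD, n = 3), and SREBF2, the transcription factor that drives the pathway, from 262 ± 30.8 to 395 ± 60.3 CPM (SD, n = 3). SC5D and MSMO1, which act on later sterols, rose by log2 fold changes of 0.88 (SE 0.21) and 1.08 (SE 0.29). Camera called the list higher (adjusted p = 9.19e-12), and the adjusted p was 0.37 with an estimated correlation. Fat absorption and lipoprotein genes had a median log2 fold change of 0.4 (0.23 without control 3), with 7 of 29 members higher and 0 lower when adjusted over the list alone, and DESeq2 called 5 higher over all genes (4 with the block, which lost APOA1). The mean log2 CPM of this list was 6.74, 6.25 and 6.64 in FOS 1 to 3 and 5.96 to 6.38 in control. Among these 7, AGPAT2 rose from 120 ± 9.95 to 200 ± 12.7 CPM, and APOA1, the main protein of high-density lipoprotein, from 980 ± 445 to 2670 ± 649 CPM (SD, n = 3). Camera called this list higher as well (adjusted p = 1.93e-07, and adjusted p = 0.442 with an estimated correlation).

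**Figure D3:**
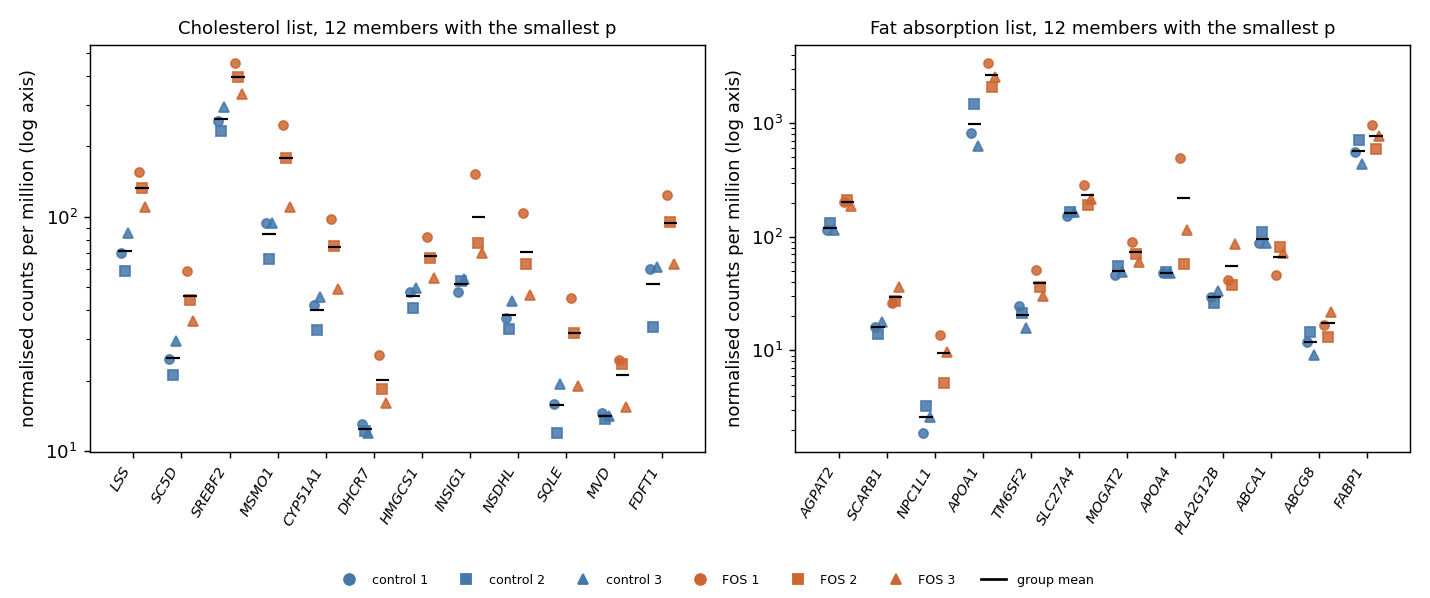
Normalised read count (CPM) on a log axis for the 12 members with the smallest p of the cholesterol list (left) and the fat absorption list (right), with a symbol for each library and a bar at each group mean. LSS lies at 71.6 CPM in control and 133 CPM in FOS, and APOA1 at 980 and 2670 CPM.

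Brush border and digestive enzyme genes of enterocytes, the absorptive cells, were called higher by camera (median log2 fold change 0.4, adjusted p = 8.76e-10), and the adjusted p was 0.35 with an estimated correlation. FABP6, an ileal bile acid carrier, belongs to the bile acid handling list and not to this one. It stood at 5753, 5155 and 4527 CPM in control 1 to 3 and at 4000, 1078 and 1505 CPM in FOS 1 to 3. TMPRSS15, the enteropeptidase, stood at 0.721 to 3.2 CPM in control and at 0.54, 11.1 and 100 CPM in FOS 1 to 3. These genes were chosen after their values were seen, and neither passed with edgeR (adjusted p = 0.503 and 0.483), although DESeq2 with the block called FABP6 lower. ASAH2 was the single member of 35 that passed when adjusted over the list alone. CDX2, AMN and ALPI had log2 fold changes of 0.85 (SE 0.24), 0.70 (SE 0.21) and 0.81 (SE 0.25) without passing with edgeR. Over all genes DESeq2 called 1 member of this list, ASAH2, and 4 with the block, which added ALPI, LCT and SI. In glycolysis and gluconeogenesis 2 of 26 members rose when adjusted over the list alone. In xenobiotic metabolism 1 of 36 members rose on the same measure, EPHX1. Over all genes edgeR called 0 members of either list, with 4 and 9 at an unadjusted p under 0.05, while DESeq2 called 2 and 3 higher (1 and 4 with the block), in the second list EPHX1, ADH1C and GSTT1. The median log2 fold change was 0.21 in the first list (0.07 without FOS 1) and 0.26 in the second (0.42 without control 2). Camera called both lists higher (adjusted p = 0.000256 and 0.000135), and their adjusted p was 0.442 and 0.35 with an estimated correlation. Camera also called higher the lists of nuclear-encoded respiratory chain genes (median log2 fold change 0.26), fatty acid oxidation (0.26), enteroendocrine cells (0.33), antioxidant defence (0.18), and nutrient and ion transporters (0.17). Their camera adjusted p was 1.33e-09, 2.68e-05, 0.000262, 0.0085 and 0.0106. In these 5 lists 0 members passed with edgeR when adjusted over the list alone, where 11, 5, 5, 6 and 6 had an unadjusted p under 0.05. DESeq2 called 1 member of the respiratory chain list over all genes, NDUFB8, and 0 of the other 4 lists. With the block DESeq2 called 0 in the respiratory chain list, 1 in enteroendocrine cells, CHGA, and 2 in the transporter list, SLC2A2 and SLC26A6. SLC2A2, a glucose transporter, stood at 1.8, 0.173 and 1.33 CPM in control 1 to 3 and at 33.4, 3.27 and 11.2 CPM in FOS 1 to 3, a log2 fold change of 3.85 (SE 0.98; 2.72 without FOS 1) with an edgeR adjusted p of 0.434 (1.91e-15 to 0.903 over all alternatives). With camera, their adjusted p was 0.579, 0.529, 0.35, 0.35 and 0.421 with an estimated correlation. Without FOS 1 the median was 0.1 in the respiratory chain list and 0.11 in fatty acid oxidation, and without FOS 3 it was 0.4 in the respiratory chain list and 0.51 in enteroendocrine cells. Without control 3 it was 0.11 in antioxidant defence. The transporter list had a median of 0.36 without control 2, and without control 1 it was not called (median 0.1, camera adjusted p = 0.101, and 7.03e-05 to 0.421 over all alternatives).

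Most markers of the muscle wall and matrix had a lower mean in FOS beside these lists, with FOS 1 the lowest library. All but 1 of 31 smooth muscle genes had a negative log2 fold change (median -0.3, camera adjusted p = 3.43e-07), as had 27 of 33 fibroblast and matrix genes (median -0.34, camera adjusted p = 2.72e-06). Their adjusted p was 0.603 for both with an estimated correlation. With edgeR 0 members of either list passed when adjusted over the list alone, where 4 and 8 had an unadjusted p under 0.05, and DESeq2 called 0 over all genes. FOS 1 had the lowest mean log2 CPM in both lists, 6.57 and 6.37, while FOS 3 had the highest mean in the matrix list, 7.1. In the smooth muscle list FOS 2 and FOS 3, at 6.98 and 7.13, lay within the control range of 6.95 to 7.41. The median of the smooth muscle list was -0.18 without FOS 1 and -0.48 without FOS 3. Without FOS 1 the matrix list was not called (median -0.15, camera adjusted p = 0.114, and 2.03e-14 to 0.603 over all alternatives). Camera also called lower the T and NK cell list (median -0.24, and -0.15 without control 3; adjusted p = 4.22e-05) and the heat shock list (median -0.17, adjusted p = 2.68e-05). Their adjusted p was 0.529 and 0.442 with an estimated correlation, and 0 members of either passed with edgeR when adjusted over the list alone. At an unadjusted p under 0.05 edgeR had 5 members in each, and DESeq2 called 1 in each over all genes, CD3D and HSP90AA1, of which the block kept HSP90AA1. CD3D, a chain of the T cell receptor complex, stood at 219 ± 4.37 and 158 ± 18.4 CPM, and HSP90AA1, a chaperone, at 2006 ± 117 and 1270 ± 123 CPM in control and FOS (SD, n = 3).

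Interferon-stimulated genes had a mean log2 CPM of 8.22 in FOS 1 and of 6.72 to 7.14 in the other 5 libraries. IFI6 stood at 2372 CPM there, at 95.5 and 77.8 CPM in FOS 2 and FOS 3, and at 203, 74.2 and 75.3 CPM in control 1 to 3. Camera called the list higher (median log2 fold change 0.29, adjusted p = 0.00632, and adjusted p = 0.736 with an estimated correlation). Without FOS 1 the call turned to lower (median -0.19, camera adjusted p = 0.00358), and without control 3 the list was not called (camera adjusted p = 0.0672). Without FOS 2 the median was 0.52. Over all alternatives the adjusted p was 2.12e-08 to 0.736. In this list 0 of 34 members passed with edgeR when adjusted over the list alone, where 2 had an unadjusted p under 0.05, and DESeq2 called 1 higher over all genes, BF2, and 0 with the block.

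Outside the lists, the named genes with the smallest unadjusted p did not pass the threshold over all genes with edgeR. VTN, an adhesive plasma protein, stood at 26.5 ± 5.04 CPM in control and 58.9 ± 1.25 CPM in FOS, and MST1 at 56.4 ± 5.67 and 107 ± 13.6 CPM (SD, n = 3). UNC5C, a netrin receptor, stood at 38.1 ± 5.65 and 20 ± 1.65 CPM (SD, n = 3). The edgeR adjusted p of these 3 genes was 0.263, 0.263 and 0.282, while DESeq2 called all 3, with and without the block. Genes of barrier and absorption and the cytokine IL1B, all of them always to be given, passed with neither edgeR nor DESeq2. IL1B was low, at 1.27 ± 0.109 CPM in control and 0.89 ± 0.129 CPM in FOS (SD, n = 3). The log2 fold change was 0.14 (SE 0.2) for the immunoglobulin receptor PIGR, 0.06 (SE 0.41) for the mucin MUC2, 0.39 (SE 0.2) for CLDN1, 0.27 (SE 0.19) for OCLN and -0.02 (SE 0.1) for TJP1, with edgeR adjusted p from 0.608 to 0.981. It was 0.85 (SE 0.36) for the glucose transporter SLC5A1, -0.51 (SE 0.36) for the peptide transporter SLC15A1, 0.07 (SE 0.26) for FABP2 and -0.51 (SE 0.33) for IL1B, with edgeR adjusted p from 0.527 to 0.953. Leaving out 1 library moved several of these values. Without FOS 1 the log2 fold change was 0.29 for SLC5A1, 0.12 for OCLN, 0.06 for PIGR, -0.57 for MUC2, 0.02 for TJP1 and -0.07 for FABP2. Without control 2 it was 0.44 for OCLN, 0.07 for PIGR and 0.04 for SLC15A1, and without control 3 it was 0.24 for CLDN1, 0.15 for OCLN and -0.12 for FABP2. PIGR gave 0.05 without FOS 2 and 0.33 without FOS 3.

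Of the 42 fixed lists with enough measured members, camera called 16, 11 higher and 5 lower, and 0 with an estimated correlation. The 9 other ways to split the 6 libraries into 3 and 3 gave 10 to 24 called lists. The exocrine pancreas list had too few measured members to be tested. The other 26 lists had camera adjusted p from 0.0612 to 0.919. With the replicate number as a block, macrophages and dendritic cells and the cell cycle were called lower (camera adjusted p = 0.0263 and 0.0155, against 0.0612 and 0.165). Without the block their camera adjusted p was 0.736 and 0.87 with an estimated correlation. The FOS libraries were not all lower. Mean log2 CPM of the macrophage list was 5.7, 5.47 and 5.55 in control 1 to 3 and 5.01, 5.81 and 5.44 in FOS 1 to 3. For the cell cycle it was 5.34, 4.89 and 5.02 in control 1 to 3 and 5.62, 4.8 and 4.42 in FOS 1 to 3. The 26 lists covered tight and adherens junctions, macrophages and dendritic cells, bile acid handling, interstitial cells of Cajal, enteric neurons and glia, crypt stem cells, the cell cycle, B cells, cytokines, the IgA network, ribosomal proteins, pattern recognition, immediate-early genes and endothelium. The rest were short-chain fatty acid uptake and sensing, granulocytes, antimicrobial effectors, thrombocytes, apoptosis, goblet cells and mucins, fatty acid synthesis, tuft cells, red blood cells, the unfolded protein response, mitochondrially encoded genes, and antigen presentation. Median, mean and test differed in sign for goblet cells (median -0.05, mean 0.02, tested higher), fatty acid synthesis (0.15, -0.05, higher), the unfolded protein response (0.02, -0.01, lower) and antigen presentation (-0.05, 0.02, higher). Of 150 annotated pathways, camera called 36, 30 higher and 6 lower, and 0 with an estimated correlation (lowest adjusted p = 0.56). Steroid biosynthesis had the smallest camera adjusted p (3.48e-10, median log2 fold change 0.86), followed by oxidative phosphorylation (1.4e-08, median 0.25, and 0.1 without FOS 1). Cytokine-cytokine receptor interaction was called lower (adjusted p = 0.000296, median -0.19).

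**Figure D4:**
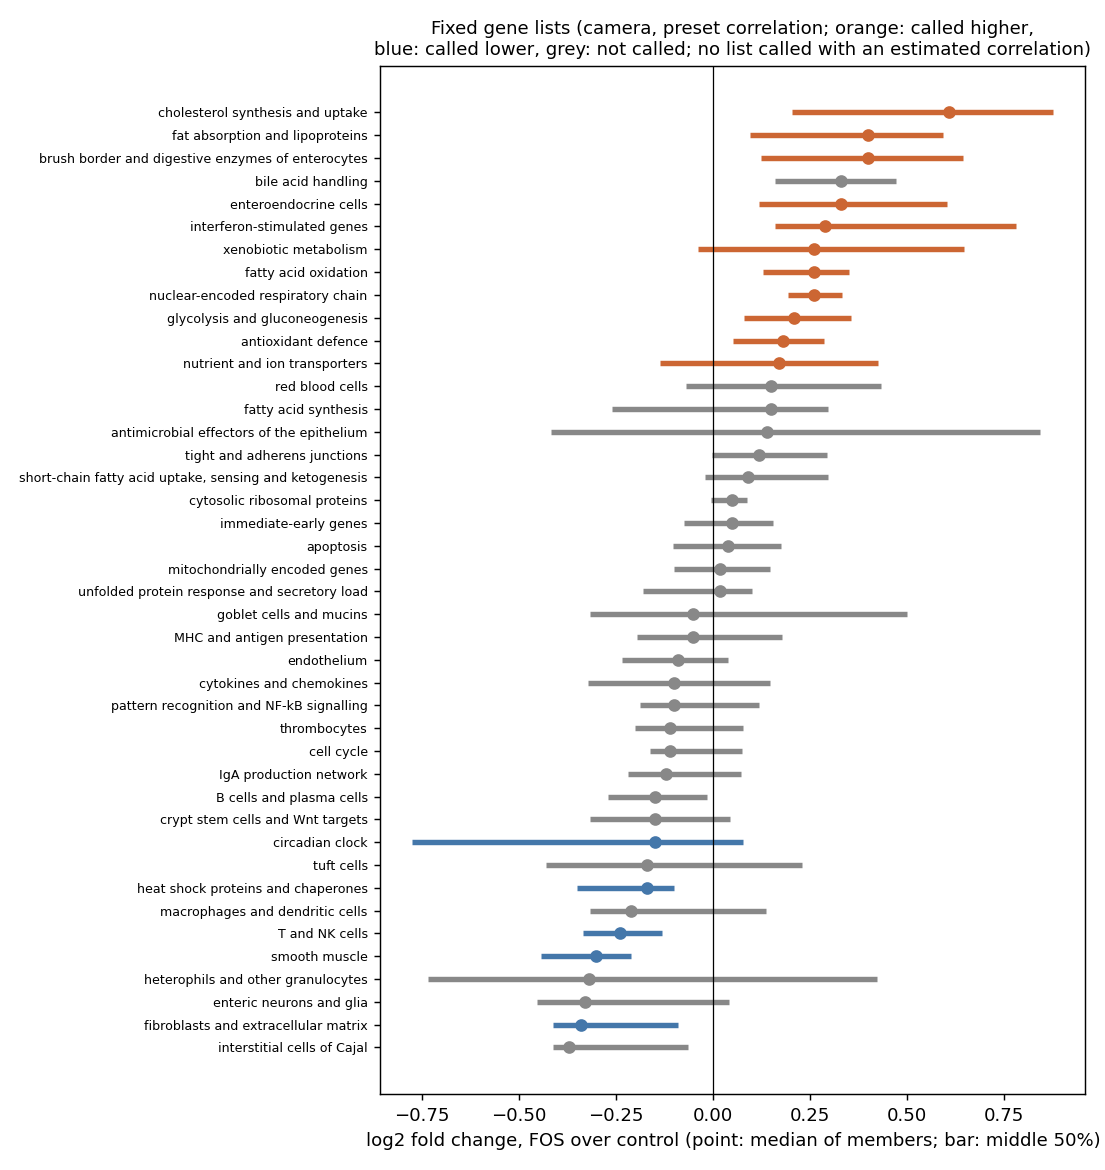
Median log2 fold change of FOS over control (point) and the middle 50% of members (bar) for each of 42 fixed gene lists. The cholesterol list lies highest at 0.61; orange and blue mark the 11 and 5 lists that camera called at its preset correlation, of which 0 were called with an estimated correlation.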

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

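The fits with W-linked transcripts or the smooth muscle list as a covariate, with only the 4 libraries that held W-linked transcripts, with robust empirical Bayes, and DESeq2 with the block were chosen after the data were examined. The 3 called genes stayed the calls under RLE and upper-quartile factors, library sizes without the most abundant and mitochondrial genes, the stricter filter, the fold threshold, robust empirical Bayes, both covariates and limma on log2(FPKM + 1) or log2(FPKM + 0.1); limma-voom with quality weights, limma on log2(FPKM + 1) without filter and leaving out assembled loci each kept 2. DESeq2 called 149 (105 higher, 44 lower), 3 of them shared, and limma-voom called 1, which was higher. With no filter 1 gene, PER3, was called lower. Leaving out a library gave 0 to 4 calls, 0 to 4 higher and 0 lower: 0 without control 1 or control 3, 1 without control 2. With only the 4 libraries that held W-linked transcripts 1 gene was called higher and 1 lower. The replicate block kept the 3 genes, all 16 lists and 35 of 36 pathways (Ribosome was lost, adjusted p = 0.0516 against 0.0344), and also called macrophages and dendritic cells (0.0263) and the cell cycle (0.0155) among 18 lists, and MAPK signaling (0.0474) and glyoxylate metabolism (0.0456) among 37 pathways; it changed no other gene, list or pathway call; DESeq2 with the block called 115 genes (87 higher, 28 lower). Called lists numbered 0 with an estimated correlation and 0 with fry's test for 1 direction (2 with its test for either direction), 26 with only the 4 libraries that held W-linked transcripts, and 15 to 23 when a library was left out. At a preset correlation of 0.05, 13 of the 16 called lists stayed called. The 3 lost were interferon-stimulated genes (camera adjusted p = 0.0879), nutrient and ion transporters (0.135) and antioxidant defence (0.103). Called pathways numbered 0 with an estimated correlation, 0 with that fry test, 8 at a preset correlation of 0.05, 2 with the smooth muscle list as a covariate, and 19 to 46 when a library was left out, the lowest without FOS 1. Mean correlation between minus within groups changed sign over all kept genes (-0.00201, exact p = 0.2). The cause of these changes was not tested.

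Of the genes not called, these changed sign. Over the libraries left out, the log2 fold change ranged from -0.44 to 3.5 for IFI6, from -0.35 to 2.38 for IFI27L1, from -0.82 to 0.46 for HINTW (Wpkci-7), from -0.57 to 0.39 for MUC2, from -0.07 to 0.02 for TJP1, from -0.76 to 0.04 for SLC15A1 and from -0.12 to 0.28 for FABP2. Without FOS 1 the log2 fold change was -0.44 for IFI6, -0.35 for IFI27L1, -0.57 for MUC2, 0.02 for TJP1 and -0.07 for FABP2. With the smooth muscle list as a covariate it was -1.39 for IFI6, -0.72 for IFI27L1, 0.28 for HINTW, -0.54 for MUC2, -0.05 for OCLN, 0.01 for TJP1 and -0.16 for FABP2. HINTW gave 0.26, 0.29 and 0.46 without control 1, control 3 and FOS 2. MUC2 gave -0.13 with limma-voom, -0.39 with quality weights, -0.2 with limma on FPKM in each of 3 forms, -0.14 with the replicate block in edgeR and in DESeq2, and -0.06 with W-linked transcripts as a covariate. With only the 4 libraries that held W-linked transcripts PIGR gave -0.04, TJP1 0.01 and SLC15A1 0.15. With quality weights TJP1 gave 0 and FABP2 -0.02. SLC15A1 gave 0.04 without control 2, and FABP2 -0.12 without control 3. The cause was not tested. At this depth and number of libraries, the self-test called 32.8% of genes changed 2-fold with edgeR, which would miss most changes of that size or less, and 62.7% with DESeq2, with 36 false calls among 154.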

Other observations

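The tests of the sampling hour and of FOS 1 alone were chosen after their results were seen, the smooth muscle covariate after the data had been examined, and the genes named first below after their values were seen.

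Several further genes varied by library. APOA4 stood at 494 CPM in FOS 1 and at 47.6 to 114 CPM in the other 5 libraries. ST3GAL4, a sialyltransferase, stood at 188 and 161 CPM in FOS 2 and FOS 3, and at 8.5 to 13.8 CPM in the other 4. GIMAP7L5 stood at 41.1, 40.6 and 41.9 CPM in control 1, control 3 and FOS 2, and at 0.289 to 0.898 CPM in the other 3.

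The 6 libraries allow 10 splits into 3 against 3, too few for a share under 0.05. The real split called 3 genes and the highest other split 1, and 1 split, the real one, called as many as 3. The real split called 16 lists and the highest other 24, and 6 splits called at least 16. The real split called 36 pathways and the highest other 38, and 3 splits called at least 36. The other 3 splits that part all 3 same-numbered pairs called 0 or 1 genes, 11 to 24 lists and 0 to 23 pathways; the remaining 6 part 1 pair each.

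The first pattern is the clock. A different share of muscle wall was argued against only weakly. With the mean level of the smooth muscle list as a covariate, all 9 clock genes that passed over the list alone kept their direction with a change above 2 SE. HLF and NPAS2 became smaller, HLF to -0.61 (SE 0.19) from -0.95 and NPAS2 to 2.13 (SE 0.16) from 2.25. The others became larger, among them BHLHE40, to -0.56 (SE 0.12) from -0.39, and CIART, to -3.87 (SE 0.88) from -2.84. The 9 genes were picked by their group difference in these same libraries, which makes a kept direction likely. Over all genes edgeR called 1 of the 9, NPAS2, with and without the covariate. The other 8 then had edgeR adjusted p from 0.199 to 0.903. A different hour of sampling in the 2 groups stays open. The measured clock genes chosen for this test were PER2, PER3, CRY2, NR1D1, NR1D2, TEF, HLF, CIART, BHLHE40 and BHLHE41. All 10 lay on the side opposite to ARNTL and NPAS2, which a shift in clock phase would give whether it came from the hour or from the diet. The labels give no hour, so these cannot be told apart, and an effect of FOS on the ileal clock is a hypothesis.

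The second pattern is the higher metabolic and enterocyte lists beside lower muscle and matrix lists. Without FOS 1, 6 of the 11 higher lists met 3 criteria that were chosen after the results were seen. The call had to be kept, with a median of at least 50% of that with FOS 1. FOS 2 and FOS 3 both had to lie above all 3 controls. The medians were 0.47 for cholesterol, 0.35 for brush border, 0.26 for enteroendocrine, 0.19 for xenobiotic, 0.17 for antioxidant and 0.15 for transporters. Some margins in mean log2 CPM were small. In the antioxidant list FOS 3 stood at 5.88 and control 2 at 5.84. In the xenobiotic list FOS 2 stood at 6.72 and control 2 at 6.67. By these criteria the 6 lists did not rest on FOS 1 alone, but criteria set after the results cannot exclude it. FOS 1 alone also stays open where 1 or 2 criteria were met, in fat absorption (2, median 0.28, with mean log2 CPM of 6.25 in FOS 2 and 6.38 in control 2), the respiratory chain (2, median 0.1), glycolysis (2, median 0.07), fatty acid oxidation (1, median 0.11) and smooth muscle (2, median -0.18). FOS 1 alone may account for the interferon and matrix lists, which met 0 (medians -0.19 and -0.15). A lower share of muscle wall stays open: of 32 muscle genes 31 were measured, MYH11, the most abundant, at 1763 ± 340 and 1309 ± 344 CPM in control and FOS (SD, n = 3), and with the list as a covariate 8 of the 16 called lists were no longer called, the muscle list itself by construction, and the interferon list turned to lower (median -0.27), while the brush border list stayed higher (median 0.26 against 0.4) as did the cholesterol list (median 0.43 against 0.61, lower quartiles 0.1 and 0.21). The bound was a median above 0.3 with the call kept, set after the data were examined but before the value was seen. The bound was met, which by itself would argue against this share for the cholesterol list. A margin for the spread of members was added after the value was seen. The lower quartile lay under the bound without the covariate as well (0.21), so a margin at that quartile could not be met and cannot decide. The share is left open because the bound too was set after the data were examined. The mean of the muscle list lay below all controls in FOS 1 only. This share and a response to FOS cannot be told apart. Other causes, among them the hour of sampling, were not tested for these lists.

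The third pattern is MSTRG.8228, read almost only in FOS. A candidate explanation is an inherited presence or absence of the locus among birds, which predicts loci with at least 10 CPM in 3 libraries and under 1 CPM in the other 3 along splits unrelated to diet. The real split alone held 1 such locus and the 9 other splits together held 1, so such a locus can occur along a split unrelated to diet. The other locus was GIMAP7L5, in the split of control 1, control 3 and FOS 2 against the rest. These 2 loci are little evidence, and neither sequence nor genotype was used here. An induction by FOS remains open.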
